A study of Danio rerio with 16 samples.

How the data were processed

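Whole zebrafish embryos were treated with cycloheximide, an inhibitor of protein synthesis, at 15 µg/ml from 1.5 hours post fertilization (hpf) and frozen at 4.7 hpf, per the labels. Each sample pooled 60 to 100 embryos. RNA was read on 2-colour Agilent arrays with 1 sample per dye channel, and 16 such channels were used here in 5 groups. Per the labels, the groups were uninjected wild type (WT, 3 samples), uninjected embryos with the spg allele m793, without maternal and zygotic Pou5f1 (MZ, 3 samples), MZ embryos injected with 100 pg Pou5f1 mRNA (MZ_Pou5f1, 3 samples), and WT or MZ embryos injected with 50 pg Sox2 mRNA (WT_Sox2, 3 samples; MZ_Sox2, 4 samples). The series design text describes the replicates as biological.

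The deposited values are probe intensity values on a linear scale. Per the submitters' processing notes the arrays were read with Agilent Feature Extraction, whose version is not given in the sources used here. Per the labels' design text, the authors split the Cy3 and Cy5 channels, quantile normalised them and treated each channel as an independent sample. The background correction is not given in the sources used here. In 14 of the 16 columns the sorted values were identical, with a median intensity of 55.07 and a highest value of 204656, while MZ_Sox2 replicate 4 and MZ_Pou5f1 replicate 2 had other distributions. These 2 columns were mapped by rank onto the distribution of the other 14, and all values were then taken to log2. Of 21555 features, 60 control features were left out and 21495 probes were tested. Columns were matched to samples by the identifier in the column header.

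In the annotation 12887 probes had 1 gene symbol, 0 had several and 8608 had none, giving 9238 distinct symbols. The RefSeq gene table of assembly GRCz12tu held the gene identifier of 12807 named probes, changed 0 symbols, and was used for names only. A gene was represented by its probe with the highest mean. The array gives no read depth, and the number of arrays limits the precision.

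All 16 samples entered 1 limma fit with a mean per group, dye as a covariate and array as a random block, because 3 arrays held 2 of the samples by their labels. The consensus correlation of that block was 0.04286, with 10 residual and 2.309 prior degrees of freedom. Moderated tests were two-sided with Benjamini-Hochberg adjustment over 21495 probes and a threshold of 0.05. The 7 contrasts, the alternatives, 17 gene lists and the rule for named genes were chosen before the data were examined. That rule named pou5f3 and sox2 in every comparison, up to 10 called genes in each direction whose groups did not overlap, and up to 4 called members of each list or, where none was called, the 2 with the largest moderated statistic. Clone names were passed over. Other called genes were chosen after their values were seen.

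Gene lists were tested with cameraPR at a preset inter-gene correlation of 0.01, adjusted over 119 tests, with an estimated correlation and fry as alternatives. The fry test asks whether the genes of a list move, on balance, one way, and does not compare the list with other genes. The lists were pluripotency and blastula regulators, SoxB1 genes, ventral and BMP pathway, dorsal organizer, mesendoderm and Nodal pathway, neural and head ectoderm, hox and caudal patterning, enveloping layer and epidermis, yolk syncytial layer and lipid transport, germ plasm and germ line, maternal egg and oocyte transcripts, early zygotic genes, immediate early genes, p53 pathway, heat shock and unfolded protein response, cell cycle, and ribosomal proteins.

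The fit was tested on simulated data for MZ against WT over 21495 probes, with the residual spread of the real probes. Of 50 probes changed by 1 on the log2 scale it recovered 10%, by 2 it recovered 62%, by 4 it recovered 82% and by 6 it recovered 92%. There were 12 calls among unchanged probes. The simulated noise was drawn independently for each probe and sample, without the structure of the real samples, so these shares need not hold for the real data. Alternatives covered the normalization, dye, block, samples in the fit, dim probes, empirical Bayes options, threshold and each replicate left out. An alternative covariate, a fit without 2 samples, sample weights and list medians against each WT sample were added after the data were seen. Computations used R 4.3.3, limma 3.58.1 and version 1.17.8 of data.table, and figures Python 3.11.15 with matplotlib 3.10.9.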

Results

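Transcript levels were compared between 16 samples of whole zebrafish embryos in which cycloheximide blocked protein synthesis, so that responses to injected Pou5f1 or Sox2 mRNA would not depend on newly made intermediate proteins. Groups are named throughout as the labels give them. The samples did not separate by those labels. Across 7668 bright probes, 6 of the 16 samples lay closest to a sample of their own labelled group, against 2.41 expected by permutation (one-sided permutation p = 0.062). The samples labelled MZ_Sox2 replicate 3 and MZ replicate 3 correlated at 0.982 (Spearman, across probes, which are not independent replicates), and those labelled MZ_Pou5f1 replicate 3 and WT replicate 1 at 0.992. The sample labelled WT replicate 3 correlated with its own group at a mean of 0.799. Every group difference below is therefore a difference between samples carrying those labels.

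**Figure D1:**
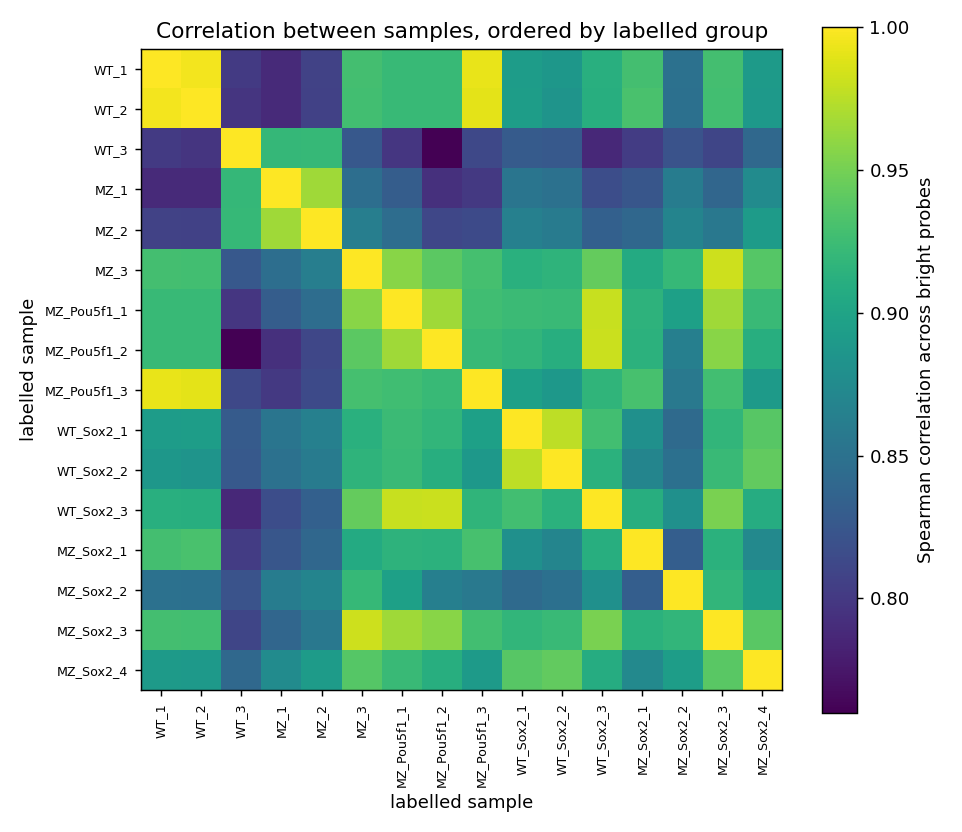
Spearman correlation across 7668 bright probes for each pair of the 16 samples, ordered by labelled group on both axes, with colour giving the correlation. The sample labelled WT replicate 3 has a mean correlation of 0.799 with its own group and 0.921 with the sample labelled MZ replicate 2.

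The gene altered in MZ embryos was read first. The pou5f3 probe, which represents zebrafish Pou5f1, was bright in every group, with a mean log2 intensity of 14.49 ± 0.46 (SD, n = 3) in samples labelled WT and 15.25 ± 0.63 (SD, n = 3) in those labelled MZ. In the samples labelled MZ_Pou5f1 its mean was 14.27 ± 0.59 (SD, n = 3). The sox2 probe had a mean of 7.33 ± 0.84 (SD, n = 3) in WT, 4.65 ± 0.52 (SD, n = 3) in WT_Sox2 and 6.42 ± 1.06 (SD, n = 4) in MZ_Sox2, so its level was not raised in the samples labelled as Sox2-injected. Neither probe passed limma's threshold over all probes in any of the 7 comparisons. Adjusted over the SoxB1 list alone, sox2 passed as lower in WT_Sox2 against WT, in MZ_Sox2 against MZ and in MZ_Pou5f1 against MZ. Adjusted over the pluripotency and blastula list alone, pou5f3 passed as lower in MZ_Pou5f1 against MZ. The probe of each injected gene thus read lower in the samples labelled as injected than in their uninjected controls. The position of the probes relative to the m793 change or to the injected mRNAs is not given in the sources used here, so neither probe checks the labels.

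**Figure D2:**
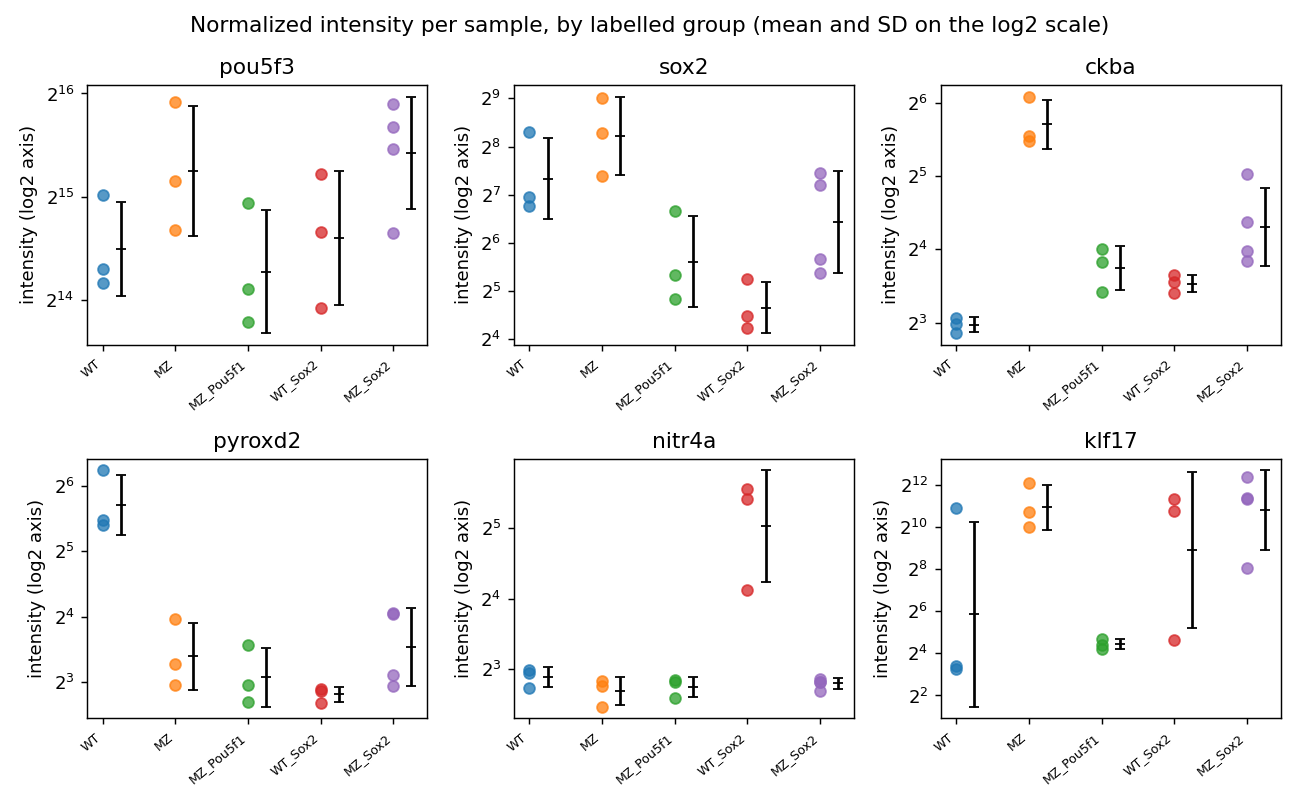
Normalized intensity of 6 genes in each of the 16 samples on a log2 axis, by labelled group, with the mean and SD on the log2 scale beside the points. The pou5f3 points stay bright in all groups, and the ckba points of MZ lie above those of WT.

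The comparison of MZ with WT asks what differs in embryos lacking functional Pou5f1 when no protein is made. The creatine kinase gene ckba was higher in samples labelled MZ, at a mean log2 intensity of 5.70 ± 0.33 (SD, n = 3) against 2.97 ± 0.10 (SD, n = 3) in WT, a difference of 2.71 (SE 0.31, adjusted p = 0.0265, limma), with all 3 MZ samples above all 3 WT samples. Within the slides that hold both groups the difference was 2.42 (1 sample per group) and 2.89 (2 samples per group). The WT intensities of 8.38, 7.93 and 7.27 lay under the 25th percentile of 9.206. They lay near the dark control feature in replicates 1 and 2 (8.237 and 7.004). In the samples labelled WT replicate 3 and MZ replicate 1 the dark feature read 52.76 and 132.7, above ckba in both. WT is therefore not separated from background, nor is MZ replicate 1, and these differences are not measured sizes. The Krüppel-like genes klf17 and klf2b, expressed early in the embryo, missed the threshold (adjusted p = 0.297 and 0.31), with means of 10.93 ± 1.07 and 13.63 ± 0.48 (SD, n = 3) in MZ against 5.85 ± 4.38 and 9.34 ± 3.64 (SD, n = 3) in WT. The SoxB1 gene sox3 had a difference of 3.63 (SE 1.08, adjusted p = 0.31) and sox1b, of the same family, had a mean of 6.02 ± 2.39 (SD, n = 3) in MZ against 10.97 ± 1.51 (SD, n = 3) in WT (adjusted p = 0.248).

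By group, 35 of 39 early zygotic genes had positive differences, with a median log2 difference of 1.82, as had 13 of 14 pluripotency and blastula regulators, with a median of 0.96, and 56 of 65 ribosomal protein genes, with a median of 0.67. The shift of the early zygotic and regulator lists was not shared by the 3 WT samples. The early zygotic median of the MZ mean minus each WT sample was 2.56, 2.68 and -0.19 for replicates 1, 2 and 3. That of the regulators was 1.53, 1.39 and -0.01. For ribosomal protein genes it was 0.82, 0.73 and 0.35, positive against each WT sample. Replicates 1 and 2 correlated at 0.996. For klf17 the WT intensities were 9.48, 10.6 and 1930, and for apoeb, an apolipoprotein gene, 165, 93.2 and 27100. These lists ranked above other genes with the preset correlation (adjusted p = 2.77e-08, 3.49e-05 and 1.24e-11). None of the 3 did so when the correlation was estimated (adjusted p = 0.628 with an estimated correlation for each). Adjusted over the list alone, klf17, klf2b and sox3 passed among the regulators, as did 9 ribosomal protein genes, rpl9 and rps6 among them, and 0 early zygotic genes did. The ventral and BMP pathway, dorsal organizer, and enveloping layer and epidermis lists also ranked higher with the preset correlation (adjusted p = 0.00422, 0.001 and 1e-04). They did not with an estimated one (adjusted p = 0.628, 0.754 and 0.628 with an estimated correlation). Against WT replicate 3 the medians of these lists were -0.12, -0.21 and -0.03, while against replicates 1 and 2 all were at least 1.6. In all, limma called 1 probe, 2615 had an unadjusted p under 0.05, and the groups did not overlap for 13.19% of probes, where chance gives 10%. The ckba call was lost with slide as a fixed block, and the second ckba probe did not move in the same direction.

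Injection of Pou5f1 mRNA into MZ embryos asks which genes respond to the protein directly. No single gene passed the threshold. The gene apoeb, an apolipoprotein, had a difference of -7.14 (SE 1.98), klf17 one of -6.51 (SE 1.59), foxb1a, a forkhead gene, one of -6.91 (SE 1.76), and sox3 one of -4.45 (SE 1.08), each with an adjusted p of 0.409. All 3 MZ_Pou5f1 samples lay below all 3 MZ samples for these genes.

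Early zygotic genes had negative differences in 37 of 39 members (median -2.68) and pluripotency and blastula regulators in 14 of 14 (median -2.31). Dorsal organizer genes, gsc among them, were negative in 17 of 18 (median -1.82), mesendoderm and Nodal pathway genes in 17 of 19 (median -2.05), and enveloping layer and epidermis genes in 20 of 24 (median -1.62). With the preset correlation 9 lists ranked lower, the smallest adjusted p being 2.51e-17, and no list did with an estimated correlation (smallest adjusted p = 0.628 with an estimated correlation). Adjusted over the list alone, 21 early zygotic genes passed, dusp6, fgf8a, tbxta and vox among them. So did 9 pluripotency and blastula regulators, foxd3, sox19a, pou5f3 and sox2 among them. Limma called 0 of 21495 probes, against 2613 with an unadjusted p under 0.05, and the groups did not overlap for 16.95% of probes, where chance gives 10%. Leaving out the sample labelled MZ replicate 3 gave 491 calls. With slide as a fixed block the neural and head ectoderm and the yolk syncytial layer lists no longer passed (adjusted p = 0.316 and 0.0583). The slide that holds the MZ_Pou5f1 samples has MZ replicate 3 as its only MZ sample, so that fit leans on it.

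The number of genes lower in MZ than WT and higher in MZ_Pou5f1 than MZ, which would be restored by the injection, was 0 by limma. The log2 differences of the 2 comparisons correlated at -0.72 across bright probes, where the shared MZ samples alone gave a median of -0.55 in 100 simulated draws, from -0.93 to 0.69. The covariance was -0.517 against a simulated median of -0.128 and range of -0.686 to 0.154, which holds it. The 3 MZ samples were too few to give each comparison its own controls, so the shared samples are not excluded as the source. For MZ_Sox2 against MZ and MZ_Pou5f1 against MZ, which also share the MZ samples, the correlation was 0.85 against a simulated median of 0.58 and range of -0.56 to 0.91, which holds it.

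Sox2 injection into MZ embryos asks what Sox2 changes without Pou5f1. Here sox1a had a difference of 1.43 (SE 0.44), axin2, a Wnt feedback gene, one of -1.34 (SE 0.35), and the mesodermal regulator tbxta one of -3.13 (SE 1.37), each with an adjusted p of 0.77. Early zygotic genes were negative in 36 of 39 members (median -1.67), dorsal organizer genes in 16 of 18 (median -1.28), and mesendoderm and Nodal pathway genes in 17 of 19 (median -1.18). With the preset correlation 6 lists ranked lower (smallest adjusted p = 2.51e-09), and 0 with an estimated correlation (smallest adjusted p = 0.628 with an estimated correlation). Limma called 0 probes, and 1036 had an unadjusted p under 0.05. No slide held both groups, so slide and injection cannot be told apart.

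In wild type embryos, Sox2 injection was associated with 21 called probes, 17 higher and 4 lower in samples labelled WT_Sox2. The oxidoreductase gene pyroxd2 fell by 2.89 on the log2 scale (SE 0.33, adjusted p = 0.0158, limma), with a mean of 5.70 ± 0.46 (SD, n = 3) in WT and 2.81 ± 0.12 (SD, n = 3) in WT_Sox2. The WT_Sox2 intensities of pyroxd2 were 7.28, 6.4 and 7.47, below the dark control feature of those samples (8.205, 7.383 and 8.653), so the fall is a bound and not a measured size. The gene lman2lb, for a lectin of the mannose-binding family, fell by 6.46 (SE 1.05, adjusted p = 0.0493), though its intensity was also low, at 184, 131 and 167, in samples labelled MZ replicate 3 and MZ_Pou5f1 replicates 1 and 2. The kinase gene rps6ka1 fell by 1.61 (SE 0.26, adjusted p = 0.0493). The steroid hydroxylase gene cyp46a1.1 fell by 1.70 (SE 0.27, adjusted p = 0.0493), to intensities of 8.23, 8.17 and 8.69 in WT_Sox2, again near background. The immune-type receptor gene nitr4a rose by 2.13 (SE 0.28, adjusted p = 0.0263), with a mean of 2.90 ± 0.14 (SD, n = 3) in WT and 5.03 ± 0.78 (SD, n = 3) in WT_Sox2.

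Other rising genes in that comparison were the parvalbumin gene pvalb7 (2.78, SE 0.45), the glucuronosyltransferase gene ugt1ab (2.61, SE 0.40) and the fetuin gene ahsg1 (2.81, SE 0.45), of whose 4 probes 3 lay in the other direction without a call. The genes prss1, fads2 and tusc3 also rose, by 1.97, 2.23 and 3.34, and were chosen after their values were seen, as their called probes are not the brightest of the gene. The remaining 10 called probes had no gene name. In WT the mean log2 intensities were 2.90 for nitr4a, 3.05 for pvalb7, 2.80 for ugt1ab and 2.80 for ahsg1. The called prss1 probe read 7.56, 7.57 and 5.98 there, and the called fads2 probe 7.11, 7.3 and 13.8. These values are near the low end of the intensity range, so the rises are bounds. No gene list passed, the smallest adjusted p being 0.0591 with the preset correlation, 3115 probes had an unadjusted p under 0.05, and the groups did not overlap for 27.35% of probes, where chance gives 10%. The count became 0 with slide as a random block and 0 with a replicate block, 0 without the sample labelled WT_Sox2 replicate 1, 0 without that labelled WT replicate 1 and 2 without that labelled WT replicate 2. No slide held both groups.

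Whether the Sox2 effect depends on Pou5f1 was tested by the difference between its effects in MZ and in WT. The gene ca15b, for a carbonic anhydrase of the germ line, had a difference of effects of -2.63 (SE 0.61, adjusted p = 0.333), atf4a, a stress-response transcription factor, one of 3.36 (SE 0.83, adjusted p = 0.347), and sox1b one of 4.75 (SE 1.38, adjusted p = 0.396). Early zygotic genes had negative differences in 32 of 39 members (median -1.19) and ribosomal protein genes in 52 of 65 (median -0.46). Both lists ranked lower with the preset correlation (adjusted p = 0.0143 and 0.00138), and neither with an estimated one (adjusted p = 0.819 and 0.794 with an estimated correlation). Limma called 0 probes, and 1954 had an unadjusted p under 0.05. With slide as a fixed block MZ_Sox2 enters this difference through replicate 1 alone. The calls of that fit are therefore not taken as results for the group.

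Between MZ_Sox2 and WT_Sox2, nitr4a fell by 2.25 (SE 0.27, adjusted p = 0.0189, limma), the mean being 2.80 ± 0.08 (SD, n = 4) in MZ_Sox2, with all 4 samples below the 3 WT_Sox2 samples. Within the slide that holds both groups, with 1 MZ_Sox2 sample (replicate 1) and 3 WT_Sox2 samples, its difference was -2.33. The MZ_Sox2 intensities of 6.46, 7.27, 7.1 and 7.1 were near the floor of the array, so both differences are bounds. The other 3 called probes had no gene name, and 1 of them, A_15_P104395, rose by 7.74 (SE 1.04, adjusted p = 0.0356). The germ line gene ca15b had a mean of 13.13 ± 0.70 (SD, n = 4) in MZ_Sox2 against 15.12 ± 0.23 (SD, n = 3) in WT_Sox2, and the keratin gene cyt1 a difference of 1.73 (SE 0.37). Both missed the threshold over all probes (adjusted p = 0.184 and 0.193) and passed when adjusted over the list alone. Pluripotency and blastula regulators were positive in 12 of 14 members (median 0.75) and enveloping layer and epidermis genes in 19 of 24 (median 0.82). With the preset correlation 6 lists passed, 5 higher and 1 lower, and 0 with an estimated correlation (smallest adjusted p = 0.628 with an estimated correlation). The only MZ_Sox2 sample on the shared slide is replicate 1, which stood apart for 8 of the 12 genes and probes flagged below. Some of those gaps lay near the floor of the array. Within that slide all 5 higher lists had medians of the opposite sign. These were -0.56 for the regulators, -0.42 for enveloping layer and epidermis, and -0.18 for yolk syncytial layer and lipid transport. They were -0.96 for early zygotic and -0.06 for ribosomal protein genes. These medians describe that sample and not the group. With slide as a fixed block the comparison rests on the same sample. The calls of that fit are therefore not taken as results for the group, and its list results are not given. Limma called 4 probes against 1627 with an unadjusted p under 0.05.

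Injected MZ_Pou5f1 embryos were set against uninjected WT to ask how far they still differ. The muscle and mesoderm regulator tbx6 had a difference of -1.16 (SE 0.47), vent, a ventral repressor, one of -1.51 (SE 0.61), and the zona pellucida gene zp3 one of 1.39 (SE 0.34, adjusted p = 0.599). Early zygotic genes were negative in 36 of 39 members (median -0.86) and mesendoderm and Nodal pathway genes in 18 of 19 (median -0.86). With the preset correlation 4 lists ranked lower (smallest adjusted p = 0.00236), dorsal organizer and yolk syncytial layer genes being the others. With slide as a fixed block none of them did (adjusted p = 0.534, 0.568, 0.91 and 0.851). Within the slide that holds both groups the early zygotic median was -0.17 and the mesendoderm median -0.05. That slide holds WT replicate 1 as its only WT sample. No list passed with an estimated correlation (smallest adjusted p = 0.628 with an estimated correlation). Limma called 0 probes, and 1557 had an unadjusted p under 0.05.

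Across all comparisons, 33 of 119 list tests passed with the preset correlation, 11 higher and 22 lower, and 0 with an estimated correlation or with fry. There were 7 lists that passed in no comparison with the preset correlation in the main fit (smallest adjusted p = 0.0673). They were SoxB1 genes, hox and caudal patterning, maternal egg and oocyte transcripts, immediate early genes, p53 pathway, heat shock and unfolded protein response, and cell cycle genes. As tested, the SoxB1 list held sox19a, sox1a, sox1b, sox2, sox21a and sox3, and the cell cycle list included ephb2b. In MZ_Pou5f1 against MZ with slide as a fixed block, SoxB1, p53 pathway and cell cycle genes passed as lower (cameraPR, adjusted p = 0.00435, 0.0194 and 0.034). The slide that holds the MZ_Pou5f1 samples has MZ replicate 3 as its only MZ sample. Within that slide the medians of these lists were -1.85, -0.23 and -0.27. These passes therefore lean on 1 MZ sample and are not taken as results for the group. Neural and head ectoderm genes passed with the preset correlation in 1 comparison (adjusted p = 0.022), yolk syncytial layer and lipid transport genes in 3 (smallest adjusted p = 0.00318), and germ plasm and germ line genes in 1 (adjusted p = 0.00633). Each has a smallest adjusted p = 0.628 with an estimated correlation. Median and mean differed in sign only for lists that did not pass, such as hox and caudal patterning genes in MZ against WT (median -0.32, mean 0.01). The test differed in sign from both for SoxB1 genes in that comparison (median 0.57, mean 0.11), ventral and BMP pathway genes in WT_Sox2 against WT (median 0.16, mean 0.11) and cell cycle genes in MZ_Pou5f1 against WT (median -0.15, mean -0.02).

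**Figure D3:**
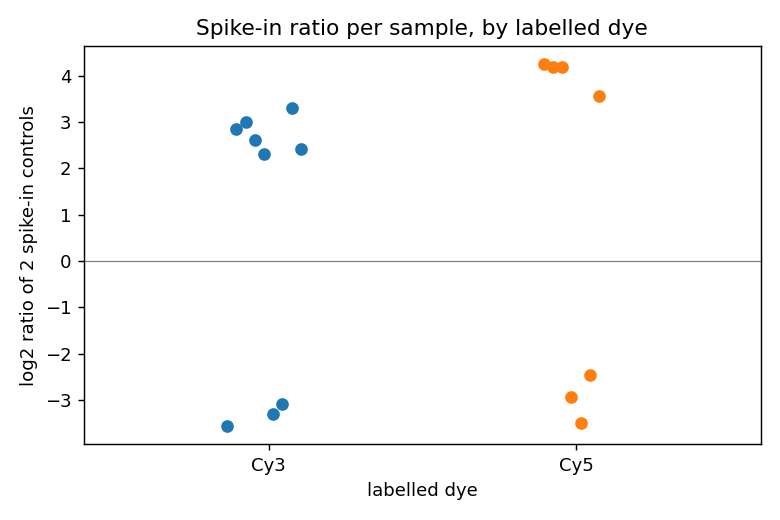
Log2 ratio of 2 spike-in controls in each of the 16 samples, by labelled dye, with 1 point per sample. Points of both dyes lie on both sides of 0, with 3 of 9 Cy3 samples and 3 of 7 Cy5 samples below it.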

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

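All tests of the label position, array notes, slide and spike-in controls were chosen after the grouping of the samples was seen, and the counts of other splits were planned.

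Samples lay closest to samples of other labelled groups, with a within-group minus between-group correlation of 0.0184 (one-sided permutation p = 0.058). A candidate explanation is that labels and value columns are displaced by 1 position: with the labels moved 1 position the value was 0.0687, the highest of 16 shifts, at p = 1e-05, the smallest that 100000 permutations can give, or 0.00016 after multiplying by 16. The closest sample then carried the same label for 15 of 16 samples, against 6 as labelled. The highest of the other shifts, 14, gave 0.0665. Most groups hold 3 samples in a row, so that shift keeps most group boundaries of the 1-position shift. The measure depends on which samples are grouped together and not on group names, so it does not single out the position sharply. Array notes moved together with the labels gave a mean dim-probe correlation of -0.031. That version stays open because the labelled array partners do not stand apart either (0.253, permutation p = 0.6). Slide alone gave 0.0315 (permutation p = 0.00668), which also stays open. Some closest pairs lay across labelled slides, such as WT replicates 1 and 2 (0.996). Others shared a slide, such as WT_Sox2 replicates 1 and 2 (0.976). No biological explanation was tested, labels were kept as given, and no gene comparison was made with moved labels.

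Spike-in controls, which no comparison used, showed 2 patterns: the log2 ratio of 2 of them was below 0 in 6 samples and above 0 in 10. The pattern did not follow the labelled dye, as 3 of 9 Cy3 and 3 of 7 Cy5 samples lay below 0 (Fisher's exact test, two-sided p = 1), and 2 of 3 labelled shared arrays carried 1 pattern in both channels. If the pattern is set by dye, a displacement of the dye notes by any number of positions is argued against, since dye and pattern agree in at most 11 samples over the 16 shifts. Whether the spike-in mixes were assigned by dye is not given in the sources used here.

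Counts of calls were compared over splits of the same samples. The 10 and 35 splits are all the possible ones, so shares out of them include the labelled split itself. For MZ against WT, 3 of 10 splits gave as many as the real 1, and the highest other split gave 5579 calls, which points to a structure of the samples that the labels do not follow. For WT_Sox2 against WT 2 of 10 splits gave at least the real 21 (highest other 35), and 10 splits are too few for a share under 0.05. Chance was not excluded for MZ_Sox2 against WT_Sox2 (2 of 35 splits, real 4, highest other 24) or the list tests (41 of 100, real 33, highest other 65). Where the real count was 0 every split gives at least as many, so the share was fixed in advance and tests nothing: 10 of 10 for MZ_Pou5f1 against MZ (highest other 4), 35 of 35 for MZ_Sox2 against MZ (highest other 14), 100 of 100 for the difference of Sox2 effects (highest other 1577), 10 of 10 for MZ_Pou5f1 against WT (highest other 1) and 100 of 100 for the restored genes (highest other 2304).

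Between MZ and WT the Sox2 effect on early zygotic genes differed by a median of -1.19 and on ribosomal protein genes by -0.46, with the preset correlation only. Of 135 genes and probes examined in MZ_Sox2, 12 had 1 sample far from the others, where chance gives about 5%, and 8 of these were the sample labelled MZ_Sox2 replicate 1. The gap divided by the range was 0.876 for hoxb1a, 0.832 for tbxta, 0.839 for id1, 0.858 for hoxb4a, 0.943 for hoxc6a and 0.89 for rpl19, and 0.954 and 0.957 for the unnamed probes A_15_P104941 and A_15_P110724, all in that sample. It was 0.836 for ccna2, 0.838 for rpl18 and 0.858 for A_15_P106133 in replicate 2, and 0.936 for zp3a.1 in replicate 3. In replicate 1, hoxb4a read 6.89 against a median of 7.87 in the other MZ_Sox2 samples, and A_15_P110724 5.82 against 7.09. Both lay below its dark control feature (7.877), so neither gap is separated from background. For A_15_P104941 the median of the others was 6.43, also near the floor. The gaps of hoxb1a (44.5 against 18.3), hoxc6a (8.63 against 96.6), tbxta (194 against 1188), id1 (235.5 against 3766) and rpl19 (15057 against 32304) reached brighter values.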

How the results depend on the processing

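Alternatives with spike-in pattern as covariate, without 2 samples and with sample weights were chosen after the results were seen, and the others before the data were examined.

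For MZ against WT the count of 1 became 0 with values centred on each median, 2 with a replicate block, 0 with only the groups compared, 0 with trend and robust eBayes, 0 with slide as a fixed block and 0 with array as a fixed block. It was 0 without the sample labelled WT replicate 1 and 16 without the sample labelled MZ replicate 3. Replicate numbers did not pair the samples, as 7 of 30 pairs correlated above 0.1, with a median of -0.145, so the replicate block has no pairing behind it.

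For MZ_Pou5f1 against MZ the count of 0 became 22 with only the groups compared. Leaving out 1 sample gave from 0, without the sample labelled MZ_Pou5f1 replicate 1, to 491, without the sample labelled MZ replicate 3. For MZ_Sox2 against MZ the count of 0 became 1 with trend and robust eBayes, and leaving out 1 sample gave from 0, without the sample labelled MZ_Sox2 replicate 1, to 13, without the sample labelled MZ replicate 2.

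For WT_Sox2 against WT the count of 21 became 36 with cyclic loess, 0 with values centred on each median, 0 with slide as a random block, 0 with a replicate block, 0 with only the groups compared, 0 with spike-in pattern as covariate and 2 without the 2 samples on another distribution. It was 0 without the sample labelled WT_Sox2 replicate 1, 0 without that labelled WT replicate 1, 2 without that labelled WT replicate 2 and 121 without the sample labelled WT_Sox2 replicate 3.

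For the Sox2 effect in MZ minus that in WT the count of 0 became 2 with only the groups compared, 65 with slide as a fixed block and 1 without the 2 samples on another distribution. It was 0 without the sample labelled MZ_Sox2 replicate 1 and 22 without the sample labelled WT_Sox2 replicate 3.

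For MZ_Sox2 against WT_Sox2 the count of 4 became 1 with values centred on each median, 2 without dye, 0 with slide as a random block, 0 with a replicate block, 0 with only the groups compared, 0 without the dimmest probes, 10 with trend and robust eBayes, 86 with slide as a fixed block, 1 with spike-in pattern as covariate and 1 without the 2 samples on another distribution. It was 0 without any 1 of the 4 samples labelled MZ_Sox2, replicate 1 included, 0 without the sample labelled WT_Sox2 replicate 1 and 97 without the sample labelled WT_Sox2 replicate 3. For MZ_Pou5f1 against WT it was 0 to 5 with 1 sample left out, the 5 without the sample labelled WT replicate 2. Restored genes numbered 12 without the sample labelled MZ replicate 3.

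Sample weights gave 5467 calls for MZ against WT, 3234 for MZ_Pou5f1 against MZ, 2 for MZ_Sox2 against MZ, 5494 for WT_Sox2 against WT, 4679 for the difference of Sox2 effects, 3741 for MZ_Sox2 against WT_Sox2, 2198 for MZ_Pou5f1 against WT and 1135 restored genes. Their estimation stopped before convergence, and it lowers the weight of samples far from their labelled group, to 0.098 for the sample labelled WT replicate 3. These counts are therefore not taken as calls. For every other count that moved, the cause was not tested.

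Of 33 list tests past the threshold, 0 remained with an estimated correlation and 0 with fry. Without dye 31 passed, 30 of them shared. With slide as a fixed block MZ_Sox2 against MZ, which holds 6 of the 33, and WT_Sox2 against WT have no list test. In that fit MZ_Sox2 against WT_Sox2 and the difference of Sox2 effects rest on MZ_Sox2 replicate 1 alone. A total for that fit is therefore not set against the 33. Among 5064 alternatives for the 249 named-gene results, 4427 were the same, 292 weaker, 133 stronger and 212 moved. With a call on either side 0 reversed, though signs turned without a call, as for sox3 in MZ_Sox2 against WT_Sox2 (-1.64 to 2.57). Most of the results named were not called, which leaves little to lose. Of the called, cyp46a1.1 was weaker in 16 of 18 alternatives, lman2lb in 14 of 18, rps6ka1 in 14 of 19, pyroxd2 in 7 of 18, and ckba in 7 of 21. Among those that rose in WT_Sox2 against WT, pvalb7 was weaker in 13 of 19, and prss1 and tusc3 each in 12 of 19. The gene ahsg1 was weaker in 11 of 19, fads2 in 10 of 19, and ugt1ab and nitr4a each in 10 of 18. In MZ_Sox2 against WT_Sox2 nitr4a was weaker in 12 of 20.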

Other observations

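These values were taken after the grouping of the samples was seen. Among bright probes, the samples labelled WT replicates 1 and 2 correlated at 0.996, with a median absolute log2 difference of 0.112. That compares with a median of 0.496 over all pairs and 0.146 for the next smallest. Identical values numbered 31 for this pair, with no count for other pairs to set it against. The labelled group accounted for a median of 35.29% of the variance of a probe, where permuted labels gave a median of 24.9% and at most 38.15%. Slide accounted for 32.55%. By the number of levels alone, chance gives 26.67% for group and 20% for slide. The first principal component held 40.07% of the variance.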
